A study of Mus musculus with 15 samples.

How the data were processed

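RNA was measured in lymphatic endothelial cells of mice of strain C57BL/6 that carried a transplanted melanoma line described as lymphangiogenic. Per the labels' protocols, tumors and lymph nodes were digested and cells were sorted as negative for CD45, the pan-leukocyte protein encoded by Ptprc, and positive for CD31 and gp38, the proteins encoded by Pecam1 and Pdpn. Total RNA of 1 ng per library was reverse transcribed and amplified with a low-input kit, per the labels' protocols. Per the same protocols, 200 pg of cDNA entered a transposase-based library preparation, and pools of 10 libraries were read as single reads of 50 bases. The 15 libraries exceed 1 such pool. No pool is recorded here for any library, so an effect of pool was not tested. The table the authors deposited holds raw counts per gene, whole numbers that were not normalized, for 21839 genes in 15 libraries. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4 and featureCounts 1.4.6 were used with genome build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here, and the kit does not mark strand, so overlapping and antisense genes cannot be told apart in these counts.

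Gene IDs were matched to GENCODE M21, an annotation of the same build. It held 21628 of the IDs, and the other 211 carried 0.0859% of all counts. The table had 20838 protein-coding genes, no gene of the mitochondrial chromosome (0 IDs) and 3899 genes with 0 counts in every library. Coordinates are those of GENCODE M21. Genes with near-identical copies, such as Ccl21a, Oas1a, the H2 class I genes and the glycolytic genes with processed pseudogenes, carry uncertain counts, because reads of 50 bases can be split or lost between copies.

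The total count per library ranged from 23830337 to 37437282, which sets the counting error behind each value. Amplified reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Pairs of libraries of 1 group differed by far more than sampling noise (the lowest mean chi-square per gene was 28.3), so no library was counted as a duplicate. Nothing in the labels says whether libraries of 1 group came from separate animals or from pools, so p-values measure the spread between these libraries.

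Each group, lymphatic cells of the tumor (Tumor), of the tumor-draining lymph node (TdLN) and of a non-draining lymph node (NdLN), had 5 libraries. Differences were tested with edgeR 4.0.16 in R 4.3.3 (robust glmQLFit and glmQLFTest, TMM factors, filterByExpr, 13887 genes tested) in 1 fit of all 15 libraries, which gives the comparisons a shared estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with their standard error (SE), derived from the quasi-likelihood F statistic, and levels as CPM (edgeR's cpm, counts scaled by library total and TMM factor), mean ± SD over 5 libraries. For 21 gene lists of functions and 13 lists of cell type markers, limma 3.58.1's camera was run on log2 CPM (prior count of 2) with a preset correlation of 0.01 between genes, and again with an estimated correlation. Lists with fewer than 3 tested members were not tested: neutrophils had 1, keratinocytes and epithelium 2. Adjustment for the list tests ran over the lists of each kind.

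The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, the named genes of a comparison were the 8 highest and 8 lowest log2 fold changes among called genes with an average log2 CPM of at least 5 and no overlap between the libraries of the groups (without predicted genes), Ch25h, up to 4 members with the smallest adjusted p of each described list, and Pdpn, Pecam1, Ptprc and Prox1. The average log2 CPM was taken over all 15 libraries, so a gene low in the compared groups could pass through the remaining group. The text names part of the genes that the rule gives. Sort markers and Prox1 check the sort, and are not findings.

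Alternatives were other scaling factors (RLE, upper quartile), no filter, a stricter filter (CPM of at least 10 in 5 libraries), DESeq2 1.42.0, limma's voom with quality weights, a fit of only the compared groups, the replicate number as a block, glmTreat against a log2 fold change of 1, each library left out in turn and, for lists, fry, an estimated correlation and a prior count of 0.5. A surrogate variable from sva 3.50.0, an immediate early score as covariate and an offset for a transcript length trend were added after seeing the data. The surrogate variable and the score were each added to a fit of only the TdLN and NdLN libraries. Exact permutation tests were used for single values. Figures were drawn with matplotlib 3.10.9.

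The edgeR and camera steps were tested on simulated data in which 200 genes had known folds, drawn at 1 CPM or more with the dispersions of the real genes. For TdLN against NdLN (13133 genes), 86.4% of genes simulated at 4-fold, 53.7% at 2-fold and 19.4% at 1.5-fold were recovered, and 1.9% of calls were false. For Tumor against TdLN (13060 genes) the shares were 77.3%, 46.3% and 17.9%, with 6% of calls false. For Tumor against NdLN (13131 genes) they were 86.4%, 50.7% and 22.4%, with 2.8% false. In the real tumor comparisons 8614 and 9230 of 13887 genes changed, against 200 simulated, so these shares may not hold there. Missed genes at 4-fold in Tumor against TdLN all had a dispersion of 0.1 or more, since 35 of the 35 with less were recovered. A criterion set at first, over 80% recovered at 4-fold, was missed in that comparison. After that result was seen, it was replaced by criteria on the accuracy of the fold, its direction and the share of false calls. In each comparison camera called the 1 list of genes simulated higher and 0 of 20 unchanged lists. The simulated genes varied independently, so camera was not tested here on lists whose genes vary together.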

Results

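Lymphatic endothelial cells were profiled by RNA sequencing from transplanted mouse melanomas, from the lymph nodes that drain them (TdLN) and from non-draining lymph nodes (NdLN), with 5 libraries in each group from mice of 10 weeks. The title of the series concerns 25-hydroxycholesterol made by lymphatic cells, so the gene of the enzyme that makes it, Ch25h, was followed in every comparison. Total counts were 31894931 to 37437282 in the NdLN libraries, 32134127 to 37043976 in the TdLN libraries and 23830337 to 34577494 in the Tumor libraries. Log2 CPM values of libraries of 1 group correlated across genes at 0.937 to 0.978, and the first principal component, which held 72.6% of the variance, separated tumor from node libraries.

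The genes of the sort markers were read first. Pdpn differed between groups by less than the spread between libraries, at 124 ± 20.7 CPM in NdLN, 120 ± 15.4 in TdLN and 116 ± 46.4 in Tumor libraries (SD, n = 5). Pecam1, an endothelial adhesion molecule, was at 1596 ± 84.6, 1179 ± 87.1 and 276 ± 86.6 CPM, and Prox1, the transcription factor that maintains lymphatic identity, at 766 ± 52.9, 538 ± 74.9 and 105 ± 22.7 CPM. Ptprc, against whose protein the cells were sorted, was low, at 5.43 ± 3.77, 1.10 ± 0.943 and 1.68 ± 1.45 CPM, and its difference between TdLN and NdLN (-2.30 ± 0.94, adjusted p = 0.215) did not pass.

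Does lymphatic endothelium of the draining node differ from that of a node that does not drain the tumor? Ch25h was lower in the draining node, at 14.4 ± 1.60 CPM against 36.2 ± 6.47 (SD, n = 5), and no TdLN library reached the level of any NdLN library. Of 31 cell cycle genes 24 rose in TdLN cells, in a list with an adjusted p = 0.088 with an estimated correlation. Immediate early genes, which respond within minutes to growth factors or stress, were lower. Ccl20, a chemokine for CCR6-positive cells, rose from 78.6 ± 33.0 to 588 ± 217 CPM, and Cxcl9, a T-cell chemokine, from 30.2 ± 14.6 to 161 ± 117 CPM. Igfbp5, an insulin-like growth factor binding protein, fell from 452 ± 163 to 114 ± 59.8 CPM.

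**Figure D1:**
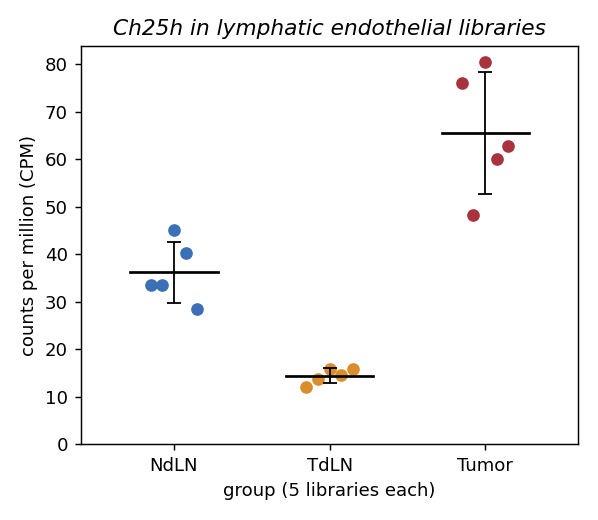
Ch25h in CPM (vertical axis, from 0) for the 5 libraries of each group (horizontal axis), with points for libraries, horizontal lines for means and error bars for SD. TdLN libraries lay between 12 and 15.9 CPM, below the NdLN libraries (28.6 to 45.0 CPM) and the Tumor libraries (48.3 to 80.4 CPM).

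In edgeR's quasi-likelihood test 484 of 13887 genes changed between TdLN and NdLN, 256 higher and 228 lower. Ch25h, ENSMUSG00000050370, lies on the minus strand of chromosome 19 from 34473778 to 34475164 in GRCm38 and encodes cholesterol 25-hydroxylase. Its log2 fold change was -1.32 ± 0.16 (SE, adjusted p = 0.00111). Of the 31 genes of the cell cycle list, 24 rose, 0 fell and 7 did not pass, and 30 rose when p was adjusted over the list alone. Plk1 (log2 fold change 2.43 ± 0.33) and Bub1 (2.39 ± 0.31), kinases of mitosis, and Kif11 (2.08 ± 0.32), a spindle motor, were among them, as were Birc5 (2.28 ± 0.38) and Cdk1 (2.23 ± 0.39). The list had a camera adjusted p = 1.4e-30, but an adjusted p = 0.088 with an estimated correlation. Outside that list, Cdca3, a cell division gene (2.13 ± 0.35), rose, as did Serinc2 (2.79 ± 0.60) and the aldo-keto reductase gene Akr1b8 (2.35 ± 0.33). Serinc2 was low in the nodes, at 0.82 ± 0.188 CPM in NdLN and 5.69 ± 6.34 CPM in TdLN libraries. Akr1b8 was low as well, at 2.20 ± 0.454 and 11.2 ± 6.24 CPM.

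Of the 18 immediate early and stress genes, 12 fell and 0 rose (15 fell adjusted over the list alone). Atf3, a stress-induced transcription factor, fell from 1166 ± 149 to 411 ± 74.0 CPM (adjusted p = 4.61e-05). Fosb (-1.62 ± 0.24), Btg2 (-1.30 ± 0.13), Zfp36 (-1.20 ± 0.14) and Fos (-1.01 ± 0.13) fell too. The camera adjusted p was 1.44e-20 and the adjusted p was 0.0145 with an estimated correlation, the only gene list of this comparison that passed that way. The lowest log2 fold changes of single genes also included Nr4a2 (-1.64 ± 0.22), an orphan nuclear receptor induced by stimulation, Apold1 (-1.66 ± 0.25), Fndc1 (-1.98 ± 0.45), the stress cytokine gene Gdf15 (-1.78 ± 0.26), the oxidase gene Duox2 (-1.76 ± 0.29) and Gpihbp1 (-1.62 ± 0.27), which encodes the endothelial anchor of lipoprotein lipase.

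For the type I interferon response, 2 of 25 members rose (14 adjusted over the list alone), with a median log2 fold change of 0.58, a camera adjusted p = 9.43e-12 and an adjusted p = 0.26 with an estimated correlation. Oas1a (1.33 ± 0.27) and the nucleic acid sensor Zbp1 (1.23 ± 0.27) rose, while Trim30a (0.80 ± 0.22, adjusted p = 0.0539) and Oasl1 (0.94 ± 0.25, adjusted p = 0.0544) did not pass. Of the interferon-gamma list 1 of 21 members rose, Cxcl9, for which TdLN 3 stood apart at 366 CPM (1 adjusted over the list alone; camera adjusted p = 0.000481, adjusted p = 0.566 with an estimated correlation). MHC class I presentation had 1 riser in 18, the peptide transporter gene Tap1 (0.72 ± 0.18; 1 adjusted over the list alone; camera adjusted p = 0.0298, adjusted p = 0.63 with an estimated correlation).

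From the TGF-beta list 4 of 17 genes fell, Ccn1 (-0.95 ± 0.11), Skil (-0.71 ± 0.12), Ccn2 (-0.69 ± 0.16) and Id3 (-0.72 ± 0.17), also 4 adjusted over the list alone, with a camera adjusted p = 0.00181 and an adjusted p = 0.0614 with an estimated correlation. Among genes of lymphangiogenesis and sprouting 3 of 20 fell, Hey1 (-1.33 ± 0.30), Flt1 (-1.81 ± 0.45) and Nrp1 (-1.52 ± 0.39). Adjusted over the list alone 6 fell and 2 rose (camera adjusted p = 0.0214, adjusted p = 0.447 with an estimated correlation). Junction and trafficking genes had 2 of 15 that fell, Jam2 (-1.79 ± 0.38) and Sphk1 (-0.47 ± 0.10), also 2 adjusted over the list alone, with a camera adjusted p = 0.0252 and an adjusted p = 0.26 with an estimated correlation. The NF-kB list had 1 faller in 16, its inhibitor gene Nfkbia (-0.46 ± 0.11; 3 adjusted over the list alone; camera adjusted p = 0.0193, adjusted p = 0.26 with an estimated correlation). Among LXR targets 1 of 11 fell, Apoe (-1.20 ± 0.22; 2 adjusted over the list alone; camera adjusted p = 0.0394, adjusted p = 0.26 with an estimated correlation). Of 14 markers of blood endothelium 3 fell, Emcn (-1.22 ± 0.23), Vwf (-1.44 ± 0.28) and Flt1, which the sprouting list also holds (5 adjusted over the list alone). The list had a camera adjusted p = 0.00615 and an adjusted p = 0.39 with an estimated correlation, while its share of all counts was 0.572% in TdLN and 0.43% in NdLN libraries.

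Camera called neither the lymphatic identity nor the sinus list between the nodes. Of 16 identity genes, Lyve1, a hyaluronan receptor, was the 1 that rose (0.78 ± 0.18), while Prox1 (-0.51 ± 0.14, adjusted p = 0.0625) and Mmrn1 (-0.61 ± 0.16, adjusted p = 0.0516) did not pass. Adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.993). Of 15 sinus markers, Ccl20, Kcnj8 (1.18 ± 0.28) and Mrc1 (1.19 ± 0.31) rose and Btnl9 (-1.20 ± 0.30) fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.226). Chemokine genes went both ways, with 3 of 24 higher, among them the scavenging receptor gene Ackr2 (0.86 ± 0.14), and 3 lower, Ccl7 (-1.46 ± 0.21), Ackr3 (-0.84 ± 0.13) and Cx3cl1 (-1.41 ± 0.24). Adjusted over the list alone 3 rose and 8 fell (camera adjusted p = 0.0782). The fatty acid transporter gene Cd36 was the 1 of 11 PPAR-gamma targets that fell (-0.88 ± 0.20), from 3325 ± 689 to 1811 ± 407 CPM (1 adjusted over the list alone, camera adjusted p = 0.219).

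**Figure D2:**
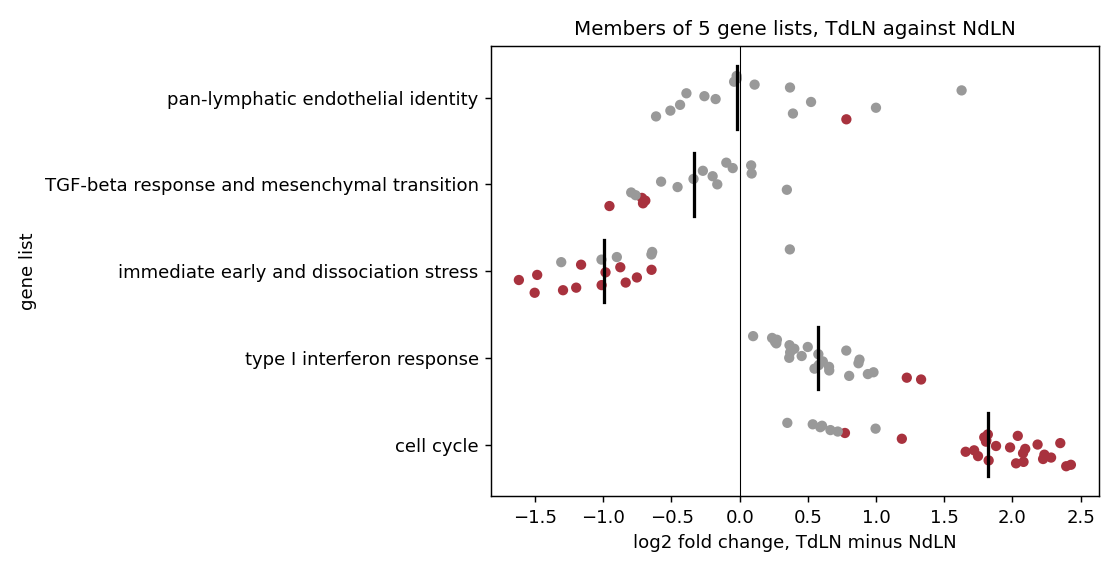
Log2 fold change, TdLN minus NdLN (horizontal axis), of each tested member of 5 gene lists (vertical axis), with red points for genes past the adjusted threshold, grey points for the others and a black line for the list's median. Cell cycle genes had a median of 1.82 and immediate early genes a median of -0.998.

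Against 484 changed genes with all libraries, the count was 225, 258 and 315 without TdLN 1, TdLN 2 or TdLN 3, and 245, 307, 277 and 319 without NdLN 2, NdLN 3, NdLN 4 or NdLN 5. Of the 51 called genes listed by name for this comparison 32 kept their call whichever library was left out, while 19, Btnl9, Ccn2, Cd36, Cxcl9, Flt1, Fndc1, Hey1, Id3, Igfbp5, Kcnj8, Lyve1, Mrc1, Nfkbia, Nrp1, Serinc2, Sparc, Sphk1, Tap1 and Zbp1, lost it in 1 or more of the 10 fits.

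How does lymphatic endothelium sorted from the tumor differ from that of the draining node? Transcripts of pigment cells were abundant in the tumor libraries. There the melanoma and pigment cell list held 3.54% ± 0.584 of all counts, against 0.00192% ± 0.000827 in TdLN libraries (SD, n = 5). That is the share of 9 marker genes alone, so the share of all RNA from pigment cells can be larger and was not estimated. Pmel, a gene of that list, had the most counts of any gene in each of the 5 Tumor libraries. The 9 tested genes of the list all rose (adjusted p = 0.0962 with an estimated correlation). They included Gpnmb (7.10 ± 1.87 to 6080 ± 1008 CPM) and Dct, a melanin synthesis enzyme (1.42 ± 1.72 to 7296 ± 1572 CPM). Ch25h was higher in tumor libraries, at 65.5 ± 12.9 CPM, with a log2 fold change of 2.18 ± 0.16 (edgeR adjusted p = 2.06e-08). Most markers of lymph node sinus endothelium were lower, and genes of hypoxia and glycolysis were higher.

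Between Tumor and TdLN 8614 of 13887 genes changed, 4434 higher and 4180 lower. In the lists below, counts adjusted over the list alone were equal to those over all genes, except that 1 cholesterol synthesis gene also fell and a PPAR-gamma target was added to those that rose (3). The largest log2 fold changes belonged to pigment cell genes, Tyrp1 (12.42 ± 0.97), Mlana (12.18 ± 0.61) and the melanosome transporter gene Oca2 (12.55 ± 0.56), and to Car14 (12.07 ± 0.55), Hhatl, Fkbp6 and the gene with the ID ENSMUSG00000102823 (12.62 ± 0.80), which GENCODE M21 lacks. Hhatl and Fkbp6 had only 2 and 3 counts in the TdLN libraries together, so their ratios, 11000 (95% counting interval 3040 to 90600) and 7480 (2560 to 36300), have wide limits. The melanoma and pigment list had a camera adjusted p = 8.26e-08 and an adjusted p = 0.0962 with an estimated correlation. Fibroblast and reticular genes rose in 10 of 12, with Col1a2 at 23.7 ± 9.77 against 1146 ± 815 CPM, Mfap5 higher by 7.93 ± 0.77 and Ccl19 lower (-5.03 ± 0.48; camera adjusted p = 0.0254, adjusted p = 0.62 with an estimated correlation). Macrophage genes rose in 10 of 11, although at low levels, with Cd68 at 15.2 ± 3.81 CPM and C1qc at 17.4 ± 7.16 CPM in tumor libraries (camera adjusted p = 0.00103, adjusted p = 0.435 with an estimated correlation).

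Of 15 sinus markers 11 fell and 2 rose, with a median log2 fold change of -4.41. Ackr4, a scavenger of CCL19 and CCL21 on sinus-lining cells, fell from 1479 ± 237 to 1.85 ± 0.984 CPM, Madcam1, an adhesion molecule of the sinus floor, from 959 ± 108 to 1.69 ± 1.16 CPM, and Itga2b from 1909 ± 336 to 5.12 ± 0.989 CPM. Dsg2, Glycam1, Clec4g, Astn1, Csf2rb2 and Marco, the other lowest genes besides Ccl20, had log2 fold changes from -10.92 to -9.92. Their counts in the tumor libraries together ran from 10 (Clec4g) to 237 (Glycam1). The list had a camera adjusted p = 3.44e-05 and an adjusted p = 0.0456 with an estimated correlation. In the same libraries the blood endothelium list, which holds Glycam1, took 0.102% ± 0.0275 of counts against 0.572% ± 0.169 in TdLN libraries. Glycam1 was at 2022 ± 278 CPM in TdLN libraries, and whether node libraries held RNA of blood endothelial cells was not tested. Of the 14 blood endothelium genes 6 fell and 4 rose (camera adjusted p = 0.457). Identity genes split, as 10 of 16 fell, among them Prox1 (-2.36 ± 0.15), Stab2 (-8.63 ± 0.34), Klhl4 (-3.17 ± 0.11) and Mmrn1 (-1.86 ± 0.17), while 2 rose, one of them Ccl21a, the chemokine that guides dendritic cells into lymphatics, from 136 ± 71.0 to 1226 ± 367 CPM (camera adjusted p = 0.00614, adjusted p = 0.386 with an estimated correlation).

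**Figure D3:**
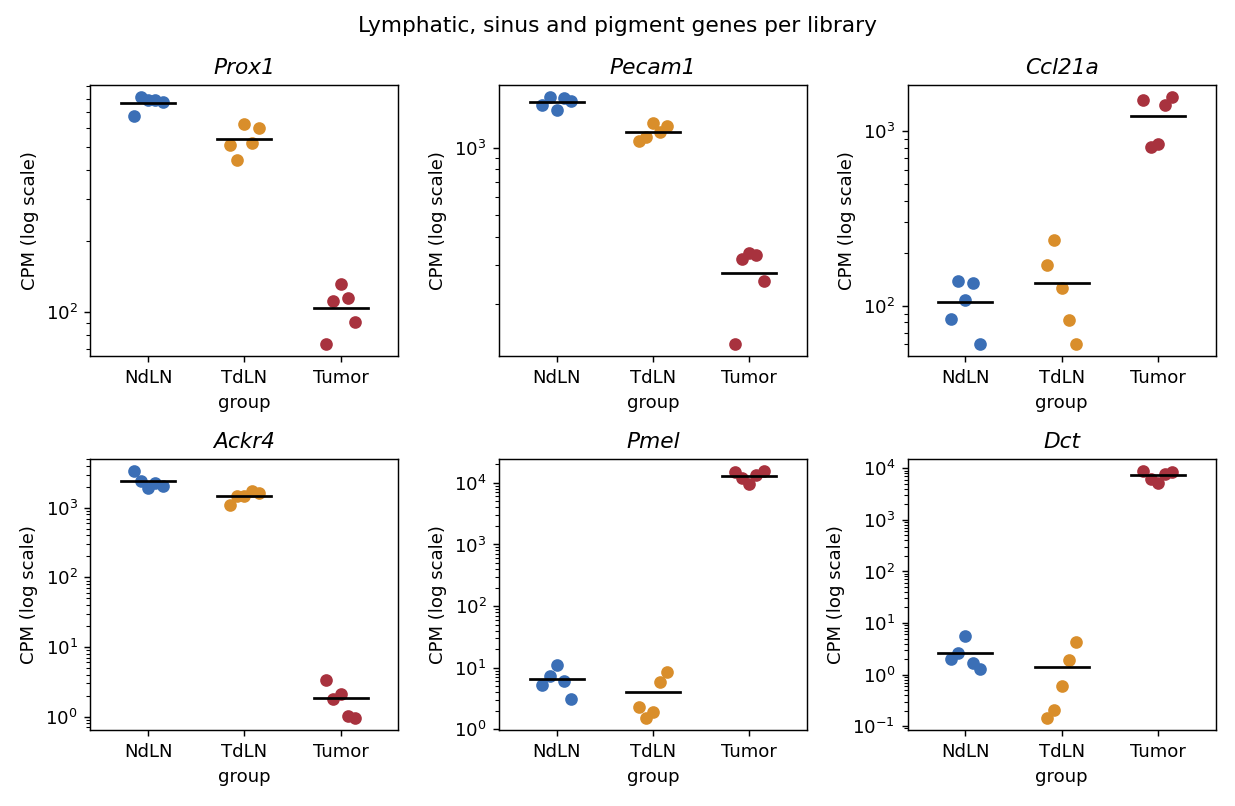
CPM on a log axis (vertical) of a lymphatic transcription factor gene, an endothelial adhesion gene, a chemokine gene, a sinus gene and a pair of pigment genes, for the 5 libraries of each group (horizontal), with points for libraries and lines for means. Mean Prox1 was 766, 538 and 105 CPM in NdLN, TdLN and Tumor libraries, mean Ackr4 2415, 1479 and 1.85 CPM, and mean Dct 2.67, 1.42 and 7296 CPM.

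In these libraries with pigment cell transcripts, hypoxia and glycolysis genes rose in 19 of 25 and fell in 1, with Eno1 at 117 ± 16.2 against 1133 ± 105 CPM, Tpi1 higher by 3.21 ± 0.13 and the hypoxia-induced carbonic anhydrase gene Car9 by 5.59 ± 0.21 (camera adjusted p = 3.01e-07, adjusted p = 0.00747 with an estimated correlation). Cholesterol synthesis genes rose in 21 of 24, among them Fdps (3.00 ± 0.24), Lss (2.86 ± 0.19), Nsdhl (2.31 ± 0.13) and Fdft1 (2.11 ± 0.17; camera adjusted p = 8.06e-07, adjusted p = 0.309 with an estimated correlation). Cell cycle genes rose in 30 of 31, with Mcm2 higher by 2.06 ± 0.20 and Rrm2 by 3.41 ± 0.41 (camera adjusted p = 6.68e-07, adjusted p = 0.399 with an estimated correlation). LXR targets went both ways, with Abca1, a cholesterol exporter, lower (-3.88 ± 0.15) and the desaturase gene Scd2 higher (2.69 ± 0.22), 3 up and 5 down of 11 (camera adjusted p = 0.322). Of 9 oxysterol genes 5 rose and 4 fell, with Hsd11b1 (3.65 ± 0.22) and Soat1 (1.69 ± 0.14) up beside Ch25h and Sult2b1 down (-4.34 ± 0.33; camera adjusted p = 0.524). Of 20 lymphangiogenic and sprouting genes 7 rose, 5 fell and 8 did not pass (camera adjusted p = 0.478). Vegfc, a growth factor of lymphatic vessels, rose to 1262 ± 103 from 3.38 ± 0.324 CPM. The melanoma line is described as lymphangiogenic, and which cells of the sorted material held these transcripts was not tested. The receptor genes Kdr (-2.59 ± 0.19) and Tek (-2.00 ± 0.17) fell.

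Of 18 MHC class I genes 16 fell, with H2-D1 (-1.98 ± 0.15) and H2-K1 (-2.19 ± 0.18) among them (camera adjusted p = 1.5e-06, adjusted p = 0.386 with an estimated correlation). The type I interferon list fell in 21 of 25, including Ifi44 (-2.04 ± 0.18) and Ddx58 (-1.95 ± 0.15; camera adjusted p = 8.35e-05, adjusted p = 0.464 with an estimated correlation). NF-kB genes fell in 13 of 16, with Vcam1 (-6.43 ± 0.28) and Icam1 (-3.04 ± 0.17), adhesion molecules for leukocytes (camera adjusted p = 3.21e-05, adjusted p = 0.0596 with an estimated correlation). Immediate early genes fell in 17 of 18, with Fos at 5337 ± 791 against 887 ± 141 CPM and Junb at 2164 ± 248 against 405 ± 25.5 CPM (camera adjusted p = 3.01e-07, adjusted p = 0.092 with an estimated correlation). Junction genes fell in 11 of 15, with Jam3 (-4.75 ± 0.20) and S1pr1 (-1.64 ± 0.12; camera adjusted p = 0.000192, adjusted p = 0.0456 with an estimated correlation). Chemokine genes fell in 13 of 24, among them Ackr3 (-1.99 ± 0.13), and rose in 7 (camera adjusted p = 0.0352, adjusted p = 0.464 with an estimated correlation). Collecting vessel and valve genes fell in 7 of 9 and rose in 1 (camera adjusted p = 0.00439, adjusted p = 0.181 with an estimated correlation). In the same libraries in which 10 of 11 macrophage genes rose, MHC class II genes rose in 8 of 12, with H2-Aa at 16.3 ± 10.5 against 192 ± 161 CPM, and Ctss fell (-2.86 ± 0.38; camera adjusted p = 0.0951). Of 17 T-cell regulatory genes 6 fell, among them Vsir (-6.02 ± 0.17) and Tnfsf10 (-4.04 ± 0.23). The 2 that rose included Lgals1 (1.99 ± 0.20; camera adjusted p = 0.154). Of the PPAR-gamma targets 5 of 11 fell, with Cd36 from 1811 ± 407 to 20.2 ± 5.32 CPM, and 2 rose (camera adjusted p = 0.184). The interferon-gamma list had 10 of 21 that fell, among them Cd274 (-2.76 ± 0.28), and 1 that rose (camera adjusted p = 0.137).

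Against a log2 fold change of 1, glmTreat called 3525 genes in this comparison. Levels here are those of sorted material with pigment cell transcripts, not of lymphatic cells alone. Tumor and node libraries also differ in organ, which cannot be told apart from the tumor in this design.

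How does lymphatic endothelium of the tumor differ from that of a node that does not drain it? Ch25h was again higher in the tumor libraries than in NdLN libraries, at 65.5 ± 12.9 against 36.2 ± 6.47 CPM, a log2 fold change of 0.86 ± 0.16 (edgeR adjusted p = 0.000175). The pigment list held 3.54% ± 0.584 of counts against 0.00229% ± 0.000803 in NdLN libraries (SD, n = 5), and all 9 of its tested genes rose (adjusted p = 0.14 with an estimated correlation). Pmel, a melanosome structural protein, was at 13090 ± 2472 against 6.63 ± 2.98 CPM. Sinus genes such as Clec4g (-10.57 ± 0.52) and Ackr4 (-10.37 ± 0.39) were lower, and cell cycle genes higher. Sinus genes had an adjusted p = 0.0527 with an estimated correlation. Cell cycle genes had an adjusted p = 0.276 with an estimated correlation.

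In this comparison 9230 of 13887 genes changed, 4715 higher and 4515 lower. Counts adjusted over the list alone were equal in the lists below, except 12 sinus genes and 4 interferon-gamma genes that fell and 1 cholesterol synthesis gene that fell. The pigment list had a camera adjusted p = 7.03e-07 and an adjusted p = 0.14 with an estimated correlation. All 31 cell cycle genes rose, with Mcm2 at 68.7 ± 5.18 against 436 ± 64.0 CPM and Plk1 at 5.73 ± 1.53 against 114 ± 7.56 CPM (camera adjusted p = 4.18e-11, adjusted p = 0.276 with an estimated correlation). Hypoxia and glycolysis genes rose in 18 of 25 and fell in 3, with Pkm higher by 2.71 ± 0.11 and Car9 by 6.16 ± 0.22 (camera adjusted p = 3.28e-06, adjusted p = 0.0188 with an estimated correlation). Among sinus markers 11 of 15 fell and 3 rose (camera adjusted p = 0.00035, adjusted p = 0.0527 with an estimated correlation). Beside them, 8 of 14 blood endothelium genes fell and 2 rose (camera adjusted p = 0.0998). That list took 0.102% ± 0.0275 of counts against 0.43% ± 0.127 in NdLN libraries. Identity genes fell in 8 of 16, including Prox1 (-2.87 ± 0.15) and Stab2 (-9.02 ± 0.35), and rose in 3, among them Ccl21a (3.55 ± 0.38) and Reln (1.35 ± 0.27; camera adjusted p = 0.0309, adjusted p = 0.427 with an estimated correlation).

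Immediate early genes fell in 17 of 18, with Fos at 10760 ± 957 against 887 ± 141 CPM (camera adjusted p = 6.64e-09, adjusted p = 0.0527 with an estimated correlation). NF-kB genes fell in 13 of 16 (camera adjusted p = 2.89e-05) and junction genes in 12 of 15 (0.000206), each with an adjusted p = 0.0527 with an estimated correlation. Chemokine genes fell in 13 of 24 and rose in 6 (camera adjusted p = 0.0219, adjusted p = 0.427 with an estimated correlation), and collecting vessel genes fell in 7 of 9 (0.00448, adjusted p = 0.176 with an estimated correlation). Cholesterol synthesis genes rose in 21 of 24 (camera adjusted p = 6.86e-07, adjusted p = 0.276 with an estimated correlation). Macrophage genes rose in 10 of 11 (camera adjusted p = 0.00267, adjusted p = 0.4 with an estimated correlation). MHC class I genes fell in 12 of 18, with H2-D1 lower by 1.98 ± 0.15 on the log2 scale (camera adjusted p = 9.76e-05, adjusted p = 0.427 with an estimated correlation). The interferon-gamma list split into 6 of 21 that rose, with Cxcl9 (2.22 ± 0.51) and Ciita (2.70 ± 0.58), and 5 that fell, with Cd274, the gene of PD-L1 (-2.60 ± 0.28), and Irf1 (-1.52 ± 0.24; camera adjusted p = 0.792). Of the type I interferon list 14 of 25 fell and 2 rose, among them Rsad2 (2.20 ± 0.34; camera adjusted p = 0.0726). Here too the libraries held pigment cell transcripts, and glmTreat called 4189 genes against a log2 fold change of 1, but not Ch25h (adjusted p = 0.998).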

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

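In each group of 5 libraries, the gap of the highest or lowest library to its neighbour was compared with the range of the group, over the total count, the genes detected, the share of the top 100 genes and the genes named in the text, and 21 of 356 such groups had a gap larger than chance gives in 1 of 20. Chance alone would give about 17.8. No pattern among them was weighed.

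Tumor 1 had the lowest total count, 23800000 (gap share 0.797), and stood apart from the other Tumor libraries in 6 results. Fdps was high there at 318 CPM (0.738), Ifi30 at 58.2 CPM (0.75) and Ms4a7 at 8.39 CPM (0.739), while Pdpn was low at 41 CPM (0.715) and Tek at 40.6 CPM (0.712). NdLN 2 was high for Ccn1 at 6670 CPM (0.712), Ccn2 at 197 CPM (0.798), Gdf15 at 286 CPM (0.862) and Nr2f2 at 83.1 CPM (0.768), and low for Serinc2 at 0.492 CPM (0.809). TdLN 3 was low for Apold1 at 180 CPM (0.894) and high for Cxcl9 at 366 CPM (0.717) and Oasl1 at 87.7 CPM (0.864). In the other NdLN libraries, Ackr2 was low in NdLN 3 at 203 CPM (0.735), Prox1 was low in NdLN 1 at 674 CPM (0.735), Cdca3 was high in NdLN 1 at 8.54 CPM (0.734) and Trim30a was high in NdLN 4 at 126 CPM (0.715). In the other TdLN libraries, Fos was high in TdLN 4 at 6710 CPM (0.73), Pdpn was low there at 93.6 CPM (0.755) and Jam2 was low in TdLN 5 at 3.61 CPM (0.812).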

How the results depend on the processing

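The surrogate variable, the immediate early score and the transcript length offset were chosen after seeing the data. Ch25h kept its direction in every fit and its call in all but 3, with adjusted p from 3.77e-11 to 0.667 for TdLN vs NdLN. Against a log2 fold change of 1, glmTreat gave an adjusted p = 0.667 for TdLN against NdLN (-1.32) and 0.998 for Tumor against NdLN (0.86), and with the immediate early score as covariate the difference was -1.34 ± 0.34 (adjusted p = 0.0731), where the fit of only these groups without the score gave -1.31 ± 0.14 (adjusted p = 0.0016) and the error was 0.142 against 0.337 with it. Over all fits of TdLN against NdLN the log2 fold change ranged from -1.40 (without NdLN 5) to -1.23 (without NdLN 3). For genes changed between TdLN and NdLN (484; 256 higher, 228 lower), DESeq2 gave 978 (466 and 512), voom with quality weights 817 (489 lower), the fit of only these groups 698 (270 and 428), the length offset 778 (418 and 360), and glmTreat 0 (0 and 0; 2440 genes had an unadjusted p under 0.05); the length offset kept 477 of the 484. Added to the fit of only these groups, the surrogate variable gave 1375 (646 and 729) and the immediate early covariate 355 (347 and 8), which held 10 of the 484. Leaving out 1 library gave 225 (without TdLN 1) to 564 (without TdLN 4), 111 to 349 higher and 111 (without NdLN 2) to 215 lower. For these counts and the values that follow the cause was not tested. The share of higher calls was 52.9%, but 97.7% with the immediate early covariate, 40.1% with voom, 38.7% in the fit of only these groups and 48% to 61.9% when 1 library was left out; other scalings shifted the median of all genes by less than 0.1. For the tumor comparisons glmTreat gave 3525 (1741 and 1784) against TdLN and 4189 (2090 and 2099) against NdLN, and all other fits stayed within 1.5 times. Gene lists past the threshold (10, 12 and 11 for TdLN vs NdLN, Tumor vs TdLN and Tumor vs NdLN) were 1, 3 and 1 with an estimated correlation, and fry gave 21 for Tumor vs TdLN and 20 for Tumor vs NdLN. Cell type lists (2, 3 and 2) were 0 in each with an estimated correlation, 1, 8 and 9 with fry, 1 for TdLN vs NdLN with a prior count of 0.5, and 1 to 5 there when 1 library was left out (5 without NdLN 1). Fry does not compare a list with other genes. Values that changed sign were Btnl9 (0.23) and Hey1 (0.054), which were called without it, with the immediate early covariate, and Pdpn with voom (0.12 against TdLN, 0.11 against NdLN); leaving out libraries gave for Pdpn, TdLN vs NdLN, -0.092 to 0.063, for Tumor vs TdLN -0.22 to 0.17 and for Tumor vs NdLN -0.25 to 0.13, and for Ptprc -0.022 to 1.08 for Tumor vs TdLN. Lists that did not pass camera and changed the direction of its test when a library was left out had median values, for TdLN vs NdLN, of -0.28 to -0.02 (basement membrane), -0.009 to 0.22 (lymphatic endothelium), -0.34 to 0.34 (macrophages), 0.021 to 0.22 (oxysterol), -0.087 to 0.061 (identity), -0.62 to 0.069 (pericytes) and -0.55 to 0.061 (red cells), and for Tumor vs NdLN of -0.53 to -0.14 (interferon-gamma), -0.27 to 0.36 (sprouting) and -0.50 to 1.24 (red cells); fry turned the list pan-lymphatic endothelial identity, TdLN vs NdLN (-0.035), and pericytes (-0.29). Same-numbered libraries did not deviate together (2, 0 and 2 of 5 correlations over 0.1; 1, 0 and 2 of 5 libraries matched their own number best). With the replicate block 400 genes changed between TdLN and NdLN, 352 of them among the 484 of the main fit. Of the genes listed by name for that comparison, 12 lost their call with the block. With it, 4 cell type lists passed for Tumor vs NdLN, and the direction of the oxysterol (0.19) and identity (-0.035) lists turned. Depth limits the ratios of Hhatl and Fkbp6, which had 2 and 3 counts in the TdLN libraries together.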

Other observations

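The tests of explanations in this part were chosen after the results were seen. Other cell type lists added little between the nodes. Of the T and NK cell list 1 of 11 genes rose and 0 fell (1 and 3 adjusted over the list alone), while the list's median was -1.78 (camera adjusted p = 0.0301, adjusted p = 0.737 with an estimated correlation). B cells (0 of 8 called, camera adjusted p = 0.0792), plasma cells (1 of 7 rose, 0.831), dendritic cells (0 of 5, 0.598), macrophages (0 of 11, 0.831), fibroblasts (0 of 12, 0.104), pericytes (1 of 8 rose, 0.977), red cells and platelets (0 of 6, 0.831), pigment cells (0 of 9, 0.0792) and lymphatic endothelium (1 of 8 rose, 0.909) did not pass. Median, mean and test differed in sign between the nodes for the oxysterol, identity, sinus, macrophage, plasma cell and pericyte lists, for TGF-beta and pericyte lists in Tumor vs TdLN, and for oxysterol, interferon-gamma, pericyte and red cell lists in Tumor vs NdLN. Further function lists that did not pass between the nodes were cholesterol synthesis (0 of 24, 0.0824), MHC class II (0 of 12, 0.263), T-cell regulation (0 of 17, 0.383), collecting vessels and valves (0 of 9, 0.183), hypoxia (0 of 25, 0.383), matrix remodelling (2 of 26 rose, Timp1 and Sparc, 0.849) and oxysterol genes (Ch25h the 1 of 9 that fell, 0.993).

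The counts of the report were also compared over 100 of the 126 ways to split the 10 libraries of a comparison into groups of 5. No other split gave as many changed genes as the real one, which was 1 of the 100 in each comparison. The counts were 484 against at most 102 for TdLN vs NdLN. They were 8614 against at most 554 for Tumor vs TdLN and 9230 against at most 1 for Tumor vs NdLN. A rank of 1 in 100 is the best these splits can give. Every other split mixes the groups, so a difference between the groups widens its spread and lowers its count. Counts of lists were matched by other splits, so they do not set the real split apart. As many gene lists passed in 5, 9 and 15 of the 100 splits (real 10, 12 and 11, highest other 10, 14 and 13), and as many cell type lists in 58, 38 and 82 (real 2, 3 and 2, highest other 9, 4 and 8). Some of these splits were close to the real one. The split with 14 lists swapped only TdLN 4 and Tumor 3, and so kept most of the real difference. A match by such a split does not show that lists pass by chance. Others, such as the split with 13 lists for Tumor vs NdLN, mixed the groups more evenly. Between the nodes, the immediate early list had its smallest p in the real split (1 of 100), the cell cycle list in 2 of 100 a p as small, the type I interferon list in 17 of 100 and the interferon-gamma list in 22 of 100.

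Ch25h and the immediate early genes were both lower in TdLN than in NdLN libraries. With a transcript length trend within each group taken out, Ch25h was at -1.33 (edgeR adjusted p = 0.000846). That trend was fitted to deviations from the group means, so a length trend that differs between the groups would remain. Whether such a trend accounts for the difference is therefore not decided. Handling or dissociation that differed between the groups could lower both, and cannot be told apart from the node itself, because the immediate early score did not overlap between the groups (8.72 to 9.70 in TdLN, 9.99 to 10.4 in NdLN). With that score as covariate the Ch25h difference was -1.34 ± 0.34, against -1.31 ± 0.14 in the same fit without it, and the call ended because the error grew (adjusted p = 0.0731). Drainage of the tumor, the biological difference the design names, stays open and untested beyond the comparison itself.

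Many sinus and lymphatic genes were lower, and Ch25h higher, in tumor than in node libraries, and the tumor libraries held far more pigment transcripts. These groups differ in organ as well as in tumor, and no lymphatic cells of tumor-free tissue outside lymph nodes were profiled. What belongs to the tumor and what to the organ therefore cannot be told apart here. Dilution by RNA of cells that lack the 8 lymphatic markers is argued against as the whole cause, since it would lower all of them alike. Their log2 fold changes against TdLN spanned 5.54, with Prox1, Mmrn1 and Lyve1 lower and Ccl21a and Reln higher. Admixed cells that hold some of these transcripts could give such unequal changes, so admixture of that kind is not decided. RNA of melanoma or other tumor cells may be a source of Ch25h. Despite the sort for CD31 and gp38, the pigment list held 3.54% of counts in the tumor libraries, a share that does not measure all RNA of pigment cells. Relative to those 8 markers Ch25h was higher in tumor than in TdLN libraries by 2.30 on the log2 scale (exact 2-sided permutation test over 252 arrangements, p = 0.00794, the smallest it can give), which largely restates its own difference and decides nothing, as no library of tumor cells alone was analysed here. Lymphatic cells of the tumor as the source stay open as well.

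Pigment transcripts appeared at low levels in every node library, at a median of 0.0077% (TdLN 1) to 0.0855% (NdLN 3) of the tumor level over 7 genes, with Dct at 5 to 202 counts. Carry-over between libraries is a candidate explanation, because 6 sinus genes appeared in turn in the tumor libraries. Their medians were 0.0314% to 0.356% of the node level, and they ranked those libraries alike (Kendall's W 0.617, permutation p = 0.0011). The highest median was that of Tumor 1, and the next was 0.106% in Tumor 3. The ranks were not tested without Tumor 1. Which tumor and node libraries shared a sequencing pool is not recorded here, so carry-over within a pool was not tested. The pigment genes ranked the node libraries alike as well (W 0.434, permutation p = 0.00024), but any other shared source of such RNA would give the same ranks. If carry-over were the source, the log2 fold changes of sinus genes such as Clec4g and Marco, and of the pigment genes, could be lower limits in size. Pigment cells that reached the draining node cannot be told apart from this, as TdLN libraries held no more than NdLN libraries (difference of log2 summed CPM -0.38, exact permutation p = 0.35), but a p of that size does not show equal levels.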
